A study of Macaca mulatta with 4 samples.

How the data were processed

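Single-cell RNA sequencing was made on rhesus macaque peripheral blood mononuclear cells, in a study of transplanted human pluripotent stem cell-derived islets. There were 4 libraries, 1 per group. They were taken before immunosuppression (Pre-IS), after it and before the transplant (Post-IS), and at 4 and 8 weeks post-transplantation (4 wpt and 8 wpt). The libraries were 10x Genomics 5' V1, read as paired 150 bp reads on an Illumina HiSeq X instrument. The processing notes of the submitters name Cell Ranger 3.1.0, Seurat 3.2.3 and the genome build Mmul_10. For each library the authors deposited a table of raw UMI counts with 15354 gene rows and a table with a cell type label per barcode. The counts carry no normalisation. Cells and genes had been chosen by the authors before deposit, and how is not stated. Cells left out by the authors could not be examined, and the labels were taken as they stand, with monocytes named by their labels CD14+ and MS4A7+.

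The tables hold 6993 cells, 16539739 UMIs and 9 cell labels, and each barcode had a label. Of 2559 gene rows that carry an identifier in place of a symbol, 400 were named from the reference table and 2159 stayed unnamed. The floor differed by class and library. A count of 0 with a floor of 3 counts allowed up to 20.9 CPM in Post-IS T cells, against 2.22 for Pre-IS, 0.946 at 4 wpt and 1.34 at 8 wpt. In MS4A7+ monocytes it allowed up to 30 CPM for Pre-IS and 21.8 for Post-IS.

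Cell class shares are percentages of all labelled cells, with exact Clopper-Pearson 95% intervals. The B lineage joins B and naive B cells. For gene levels, UMIs were summed over the cells of a class in a library and divided by the class total, as CPM. The ratio of a pair of libraries has an exact conditional binomial 95% interval. Where 1 library had 0 UMIs the fold is taken against a floor of 3 counts in that library and described with "at least". It leaves out the counting error of the other library, so the exact 95% bound is lower. For PF4 in CD14+ monocytes, Post-IS over Pre-IS, that bound was 7.69 against 10.2. With 1 library per group no test between groups was made. Classes with at least 50 cells in both libraries were compared.

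The comparisons were Post-IS with Pre-IS, 4 wpt with Post-IS, 8 wpt with Post-IS, and 8 wpt with 4 wpt. Up to 3 higher and 3 lower genes were named in each of the 3 classes with most cells. They were ranked by the interval bound nearest to 1, which had to lie beyond 1.5-fold. A gene needed at least 20 UMIs over both libraries and UMIs in at least 5% of cells of 1 library. Genes without a symbol, ribosomal, mitochondrial, hemoglobin, immunoglobulin and T cell receptor genes were passed over. So were genes below 10% of the CPM of their highest class in both libraries, to avoid free RNA.

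There were 28 gene lists, of which 26 were compared and 2 (islet endocrine and Y-linked genes) are given as values. The lists cover cytotoxic effector, naive and central memory, activation, calcineurin-NFAT, regulatory and inhibitory receptor genes of T cells, naive and memory B cells, and classical and nonclassical monocytes. They also cover type I interferon, interferon gamma, glucocorticoid-induced, immediate early and heat shock, NF-kB, MHC class II, proliferation, mTOR and glycolysis, apoptosis and p53, and chemokine receptor genes. The last ones hold genes of T cells, B cells, monocytes, platelets, red cells and neutrophils, read where they belong to another cell type. Of those, all 8 B cell genes, 8 of 10 monocyte genes, 2 of 11 neutrophil genes and 1 of 8 T cell genes also stand on another list. A list value is the median log2 ratio of CPM over members with at least 20 UMIs in both libraries together, with an offset of 0.5 UMIs, and needed at least 3 members. Its interval comes from 1000 Poisson redraws of the counts. It was set against 10000 random lists of the same size, matched on mean CPM in 20 bins. A list outside the 2.5 to 97.5 percentiles of these is described as outside the random range. This held for 77 of 207 list values. Of lists of unrelated genes 5% would lie outside by construction. Members of a list can move together, lists share members and most comparisons use the same Post-IS library. The 5% is therefore not an expected share for these lists. Medians were also taken with members of 0 UMIs at their floor, a step added after the data were seen. The random lists were not given this step.

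Groups, comparisons, lists, the naming rule and the alternatives were set before the data were examined. Alternatives were other scalings (TMM of edgeR and median of ratios), each cell weighted equally, cells thinned to 1000 UMIs, possible doublets left out, and totals without ribosomal, mitochondrial, hemoglobin and immunoglobulin genes. Further ones were a minimum of 50 UMIs or none, an offset of 2 UMIs, the labels of a lineage pooled, shares among cells of at least 1000 UMIs, shares without cells whose markers disagree with their label, and shares without platelets. A possible doublet had UMIs from at least 2 markers of each of at least 2 of T cells, B cells and monocytes, and there were 44, 5, 81 and 79 in the libraries in order of time. Comparisons of 4 wpt and 8 wpt with Pre-IS were added after the data were seen, because the Post-IS library had the fewest cells and UMIs. So was the cytotoxic list in T cells with a CD3 UMI and no KLRF1 or NCR1 UMI, first for Post-IS over Pre-IS, where what would count against it was set before its value was seen, and then for the other comparisons. The lists followed most closely across alternatives were the highest and lowest per class and comparison among those outside the random range with at least 8 members, a rule set after the medians were seen.

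The procedure was tested on simulated Poisson counts with 200 genes altered. Such counts hold no clustering of UMIs by cell and no difference between blood draws. The intervals are exact for them, so their coverage was set in advance and the rates are not error rates of these data. In simulated T cells, Post-IS over Pre-IS, 97.4% of intervals covered the true ratio. The 1.5-fold bound, without the filters on cells and background, passed 0.125% of unaltered genes. It found 86% of genes raised 4-fold and 30% of genes lowered 4-fold. Of genes altered 2-fold it found 12% and 4%, so most differences near 2-fold go unnamed there. For 8 wpt over 4 wpt 100% of genes raised and 78% of genes lowered 4-fold were found, against 58% and 36% for genes altered 2-fold. Of 40 unaltered lists per setting, between 1 and 3 lay outside the random range. Python 3.11.15 was used with numpy 2.4.6, scipy 1.17.1 and pandas 2.3.3, and R 4.3.3 with edgeR 4.0.16.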

Results

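Single-cell RNA sequencing profiled macaque peripheral blood mononuclear cells from a study of transplanted human stem cell-derived islets, in 4 libraries taken at different times. The Pre-IS library was taken before immunosuppression and the Post-IS library after it had been given but ahead of the transplant. The 4 wpt and 8 wpt libraries were taken 4 and 8 weeks after transplantation. The deposited tables held 1928 cells for Pre-IS, 603 for Post-IS, 1882 for 4 wpt and 2580 for 8 wpt. Their totals were 3356133, 791030, 6910432 and 5482144 UMIs (unique molecular identifiers, each standing for 1 captured RNA molecule), in that order. The median depth per cell was 1563, 1168, 3551 and 1877 UMIs, so the Post-IS library was the smallest and the shallowest. Mitochondrial genes took 1.36% of its UMIs, against 0.653% for Pre-IS, 0.948% for 4 wpt and 0.741% for 8 wpt. Each group was 1 library, so no difference could be held against a spread between replicates, and every interval covers counting error alone. Intervals of gene levels and lists treat UMIs as independent and leave out their clustering in few cells, so they can be too narrow. In Post-IS T cells, for example, the 53 UMIs of granzyme B sat in 10.4% of cells. The labels do not name the drugs and do not say whether all libraries came from the same animal.

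The balance between lymphocytes and monocytes differed widely among the libraries. Lymphocytes made up 81.3% of Pre-IS cells (95% exact binomial interval 79.5 to 83.0), 23.1% of Post-IS cells (19.8 to 26.6), 70.6% at 4 wpt (68.5 to 72.6) and 83.0% at 8 wpt (81.4 to 84.4). Monocytes took 17.2% (15.5 to 18.9), 76.3% (72.7 to 79.6), 27.6% (25.6 to 29.7) and 15.9% (14.5 to 17.4) of the cells of these libraries. Dendritic cells, the antigen-presenting cells of blood, were scarce throughout, at 1.56% for Pre-IS, 0.663% for Post-IS, 1.22% at 4 wpt and 1.12% at 8 wpt. Platelets were labelled at 4 wpt alone, where they were 12 cells or 0.638% (0.330 to 1.11). With a floor of 3 cells, a count of 0 allowed a platelet share of up to 0.156% for Pre-IS, 0.498% for Post-IS and 0.116% at 8 wpt, and the exact intervals ended at 0.191%, 0.610% and 0.143%.

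**Figure D1:**
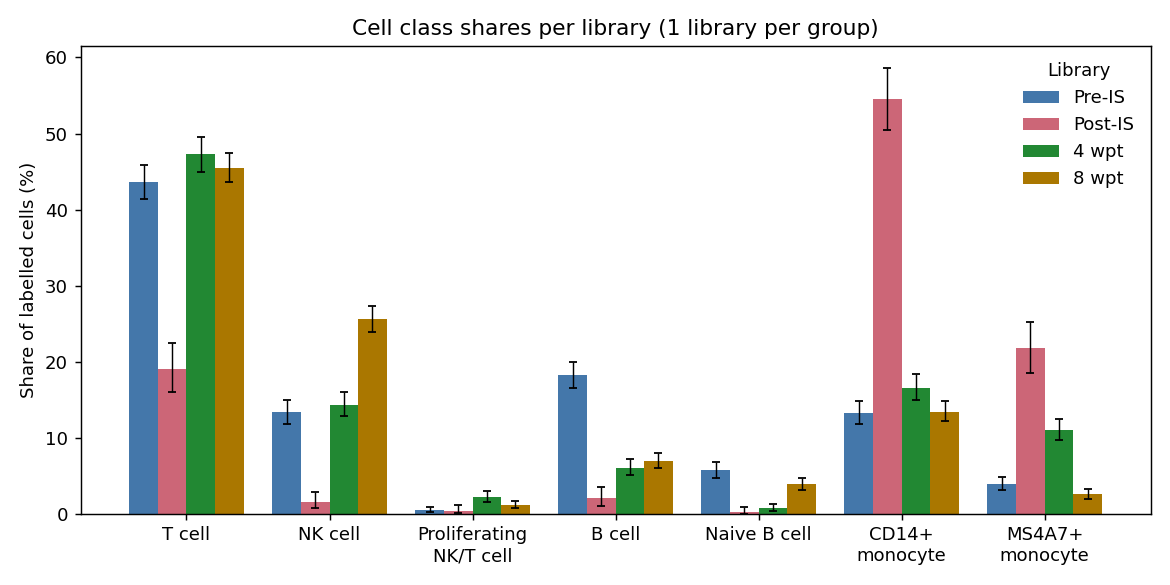
Share of labelled cells (%, vertical axis) in 7 cell classes (horizontal axis), 1 bar per library, coloured by library, with 95% exact binomial intervals as error bars. CD14+ monocytes take 54.6% of Post-IS cells and between 13.3% and 16.6% of the cells of the other libraries, and T cells take 19.1% of Post-IS cells against at least 43.6% elsewhere.

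The step from Pre-IS to Post-IS covers the start of immunosuppression, before any islets were given. Post-IS blood held 8.93-fold fewer NK cells by share, at 1.49% (0.685 to 2.81) against 13.3% (11.8 to 14.9), and 11.1-fold fewer cells of the B lineage, at 2.16% (1.15 to 3.66) against 23.9% (22.0 to 25.9). Naive B cells were a single cell of 603, or 0.166%, against 5.71% for Pre-IS. T cells were 2.29-fold lower, at 19.1% (16.0 to 22.4) against 43.6% (41.4 to 45.9). CD14+ monocytes, the classical class, were 4.11-fold higher by share at 54.6% (50.5 to 58.6) against 13.3% (11.8 to 14.9). MS4A7+ monocytes, named for a membrane protein typical of nonclassical monocytes, were 5.59-fold higher at 21.7% (18.5 to 25.2) against 3.89% (3.07 to 4.85). Counting cells of at least 1000 UMIs alone gave a Post-IS share of 24.2% for T cells and 69.0% for monocytes. The shallowest cell held 289 UMIs for Post-IS, against 521 for Pre-IS, 697 at 4 wpt and 653 at 8 wpt. The depth of the cells kept thus differed by library. Shares are relative, so a higher share of 1 class can stem from fewer cells of the others.

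Genes of cytotoxic effector cells were lower in Post-IS T cells. Granzyme B (GZMB), the protease that cytotoxic cells deliver to their targets, stood at 369 CPM (UMIs per 1000000 UMIs of the class) against 1865 CPM, 5.06-fold lower (3.85 to 6.77). CX3CR1, the fractalkine receptor of circulating effector cells, had 0 UMIs against 188 and was at least 6.67-fold lower. The chemokine CCL4L1 was 11.4-fold lower (4.43 to 42.1). Of 21 measured genes of the cytotoxic effector list, 16 were at least 1.5-fold lower, 0 were higher by that much and 5 lay between. The list median was -1.36 on the log2 scale (-1.78 to -1.08), outside the -0.26 to 0.24 that held 95% of random lists of like expression, and -1.18 with its 4 genes of 0 UMIs at their bound. Naive and central memory genes had a median of 0.43 (0.22 to 0.63), with 5 of 12 at least 1.5-fold higher. LEF1, a transcription factor of naive T cells, was 2.03-fold higher (1.57 to 2.59). Also higher by the naming rule were RFK, the riboflavin kinase, 3.54-fold (2.01 to 6.03), SESN3, a sestrin, 4.51-fold (2.06 to 9.31), and WDR47, 5.64-fold (2.18 to 13.8).

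Within T cells, glucocorticoid-induced genes had a median of 0.63 (0.14 to 0.72), with 7 of 14 higher and 1 lower. Its members BIRC3 and CXCR4 were 2.35-fold (1.32 to 3.98) and 1.81-fold higher (1.14 to 2.77). Immediate early and heat shock genes had a median of 0.34 (0.06 to 0.51), with 4 of 16 higher and 3 lower. Several further T cell lists lay within the range of random lists. Their medians were 0.24 for T cell activation, 0.31 for the calcineurin-NFAT early response, -0.37 for regulatory T, -0.30 for inhibitory receptors, -0.12 for mTOR and glycolysis, and -0.04 for proliferation. The T cell levels of CD4 (83.5 CPM against 119), CD8A (76.5 against 191) and CD8B (69.6 against 94.1) rested on 10 to 12 Post-IS UMIs each, and the intervals parted for CD8A alone (38.2 to 137 against 169 to 216).

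CD14+ monocytes of the Post-IS library were higher in steroid-responsive, early-response and inflammatory genes, and lower in MHC class II genes. JUN, a subunit of the AP-1 transcription factor, was 7.06-fold higher (5.26 to 9.63), at 682 CPM against 96.7 CPM. Of 19 immediate early and heat shock genes 12 were at least 1.5-fold higher and 0 lower, with a median of 0.74 (0.57 to 1.06). EGR1 was 4.62-fold (3.37 to 6.44) and FOS 2.42-fold higher (2.25 to 2.60). The glucocorticoid-induced list had a median of 0.85 (0.73 to 1.09), with 11 of 14 higher and 0 lower. Among its members DDIT4, an inhibitor of mTOR signalling, was 5.40-fold higher (2.85 to 11.1), CEBPD 3.31-fold (2.72 to 4.04) and the MAP kinase phosphatase DUSP1 2.80-fold (2.51 to 3.13). NF-kB and inflammatory cytokine genes had 6 of 11 higher and a median of 0.69 (0.29 to 1.02), with PTGS2, the inducible cyclooxygenase, 3.56-fold higher (2.40 to 5.39). MHC class II presentation genes had a median of -0.48 (-0.52 to -0.35). MAMU-DRA, an MHC class II alpha chain, was 1.53-fold lower (1.44 to 1.62), and 3 of 11 members passed 1.5-fold.

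Nonclassical monocyte genes were also higher under the CD14+ label, with 7 of 12 higher and a median of 0.83 (0.47 to 1.11), or 0.45 with the monocyte labels pooled. C1QB, a chain of complement C1q, was 4.99-fold higher there (2.62 to 10.3). Platelet genes stood at a median of 2.96 over 3 measured members, and at 1.87 with no UMI minimum. PF4, a platelet chemokine, had 25 UMIs against 0 and was at least 10.2-fold higher, and these UMIs sat in few of the cells. THBS1, the adhesive glycoprotein thrombospondin 1, was 17.5-fold higher (5.61 to 88.3), on 3 Pre-IS UMIs, and its log2 ratio of 3.93 was 2.39 in cells thinned to 1000 UMIs. The lowest named genes were HVCN1, a voltage-gated proton channel, 4.33-fold (1.90 to 11.5), STMN3, a stathmin, 6.00-fold (1.80 to 31.3), and PMPCA, a subunit of the mitochondrial processing peptidase, 7.37-fold lower (1.76 to 65.5).

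MS4A7+ monocytes also held more of the steroid-responsive transcripts. FKBP5, a glucocorticoid receptor co-chaperone that glucocorticoids induce, was 6.82-fold higher (2.73 to 22.0) and stood at 341 CPM. The glucocorticoid-induced list had 8 of 12 members higher, 0 lower and a median of 1.00 (0.64 to 1.19). The scavenger receptor CD163 was 4.11-fold higher (1.71 to 12) and TSC22D3, known as GILZ, 2.20-fold (1.5 to 3.28). Classical monocyte genes had a median of 0.92 over 5 members, which became -0.22 with no UMI minimum and 0.08 with the monocyte labels pooled. The NF-kB list stood at -0.57 over 4 members and turned to 0.53 with the labels pooled. Apoptosis and p53 genes had a median of 0.46 over 8 members, and -0.003 with a minimum of 50 UMIs. BTG1, an antiproliferative factor of that list, was 3.06-fold higher (2.21 to 4.32). AKR1A1, an aldo-keto reductase, was 4.13-fold lower (1.97 to 9.48), ROGDI 4.13-fold (1.80 to 10.7) and NMRAL1 5.86-fold lower (1.91 to 23.9). In cells thinned to 1000 UMIs the log2 ratio of FKBP5 went from 2.65 to 4.74 and that of NMRAL1 from -2.42 to -0.75. The zinc finger gene ZC3H10 was 2.51-fold higher (1.99 to 3.18). Its T cell level of 3884 CPM for Pre-IS, 7271 for Post-IS, 1936 at 4 wpt and 2787 at 8 wpt ran opposite to the depth of the libraries, and whether its reads were assigned correctly was not tested, so its ratios may not be read as expression.

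**Figure D2:**
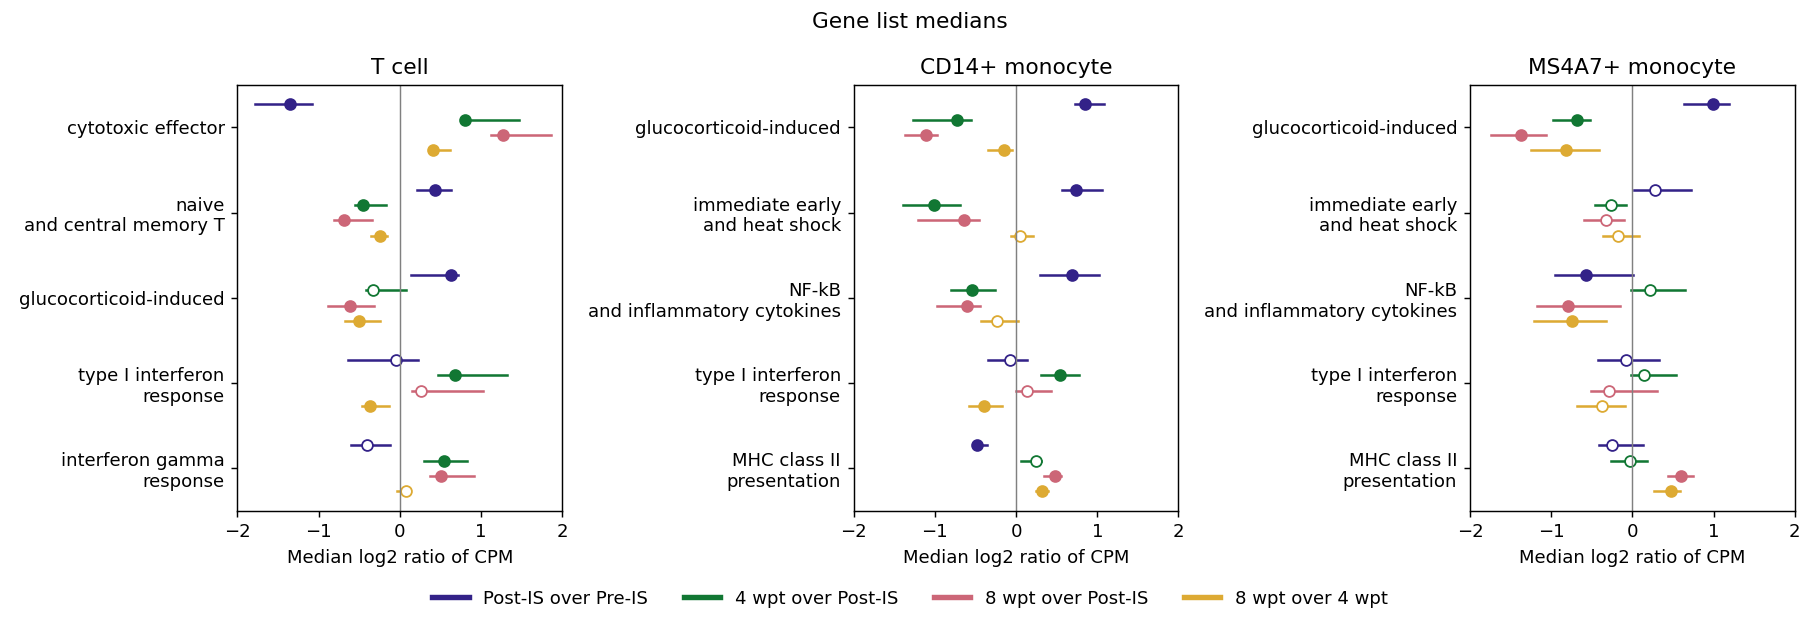
Median log2 ratio of CPM (horizontal axis) of 5 gene lists in each of 3 cell classes, 1 point per comparison, coloured by comparison, with 95% counting intervals as lines. Filled points lie outside the range of 95% of random lists and open points inside it. The cytotoxic list in T cells stands at -1.36 for Post-IS over Pre-IS and at 0.81 and 1.27 for 4 wpt and 8 wpt over Post-IS.

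The comparison of 4 wpt with Post-IS asks what differed in the blood a month into the graft relative to the last sample before it. Lymphocytes were 3.06-fold higher by share and monocytes 2.77-fold lower. NK cells were 9.61-fold higher, at 14.3% (12.8 to 16.0) against 1.49%. T cells were 2.48-fold higher, at 47.2% (45.0 to 49.5). The B lineage was 3.16-fold higher at 6.80% (5.71 to 8.03). Proliferating NK and T cells formed 2.18% of cells (1.57 to 2.94), against 0.332% (0.0402 to 1.19) in the Post-IS library. CD14+ monocytes were 3.29-fold lower at 16.6% (14.9 to 18.3) and MS4A7+ monocytes 1.98-fold lower at 11% (9.62 to 12.5).

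In T cells, cytotoxic genes stood above Post-IS at 4 wpt. GZMB was 3.43-fold higher (2.62 to 4.59) at 1265 CPM, granzyme A (GZMA) 4.71-fold (1.83 to 17.4) and CX3CR1, with 270 UMIs against 0, at least 4.08-fold higher. With each cell weighted equally the log2 ratio of GZMB went from 1.765 to 1.306. The cytotoxic list had 15 of 23 genes higher, 0 lower and a median of 0.81 (0.76 to 1.47), or 0.74 with its 4 genes of 0 UMIs at their bound. Set against Pre-IS instead, a comparison chosen after the data were seen, the same list stood at -0.30, so its direction depended on the reference library. Naive and central memory genes had a median of -0.46 (-0.56 to -0.18), with 5 of 13 lower and 1 higher, and 0.02 against Pre-IS. LEF1 was 2.0-fold lower (1.57 to 2.53). The gut-homing receptor CCR9 was 9.65-fold lower (4.76 to 18.6), the transcription factor RFX1 5.36-fold (2.96 to 9.20) and ZC3H10 3.76-fold (3.51 to 4.01). UQCRB, a subunit of respiratory complex III, was 15.5-fold higher (2.76 to 614), on 1 Post-IS UMI.

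Interferon-induced genes were higher at 4 wpt in T cells and CD14+ monocytes. IFI27, a type I interferon-induced mitochondrial protein, was 7.56-fold higher (3.13 to 23.8) in CD14+ monocytes, and 3.36-fold higher (1.43 to 10.4) in T cells at 117 CPM. In CD14+ monocytes the type I interferon list had 12 of 24 genes higher, 0 lower and a median of 0.54 (0.31 to 0.78). The antiviral regulator IRF7 was 4.07-fold higher there (1.77 to 11.5). In MS4A7+ monocytes the type I interferon list stood at 0.15, inside the random range. In T cells the list had 19 of 30 genes higher, 0 lower and a median of 0.68 (0.47 to 1.32). Because 7 of these genes had 0 Post-IS UMIs in T cells, the median was 0.22 with them at their bound, and 0.16 with an offset of 2 UMIs. The random range of -0.26 to 0.30 was taken without either step. Whether these lower medians lie outside a random range is therefore not settled. Interferon gamma genes had medians of 0.54 (0.29 to 0.83) in T cells, with 3 of 8 higher, and 0.31 (0.11 to 0.41) in CD14+ monocytes, with 1 of 11 higher and 2 lower. Against Pre-IS they were 0.14, inside the random range, and 0.29. IRF1, a transcription factor induced by interferon gamma, was 2.55-fold higher in T cells (1.54 to 4.57), and the immunoproteasome subunit PSMB8 1.47-fold in CD14+ monocytes (1.23 to 1.77).

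Early-response genes, and part of the NF-kB and inflammatory cytokine list, were lower than at Post-IS in CD14+ monocytes. NR4A1, an early-response nuclear receptor, was 30.1-fold lower (14.7 to 71.9), EGR1 22.5-fold (14.4 to 36.8) and JUN 17.8-fold (13.0 to 24.9). The log2 ratio of NR4A1 was -4.83, and -3.86 in cells thinned to 1000 UMIs. The immediate early and heat shock list had 13 of 19 genes lower, 0 higher and a median of -1.01 (-1.39 to -0.70), or -0.56 with the monocyte labels pooled and -0.36 against Pre-IS. The glucocorticoid-induced list had 8 of 15 lower, 0 higher and a median of -0.73 (-1.26 to -0.55), or -0.20 against Pre-IS, with DUSP1 7.01-fold lower (6.24 to 7.88). NF-kB genes had a median of -0.54 (-0.81 to -0.27), and 0.09 against Pre-IS, with 5 of 11 lower and PTGS2 19.1-fold lower (10.9 to 36.2). The median was -0.73 for apoptosis and p53 genes, with 7 of 13 lower, and -3.35 for 3 platelet genes. Nonclassical monocyte genes had 7 of 12 lower and a median of -1.06 (-1.28 to -0.72). This became -0.12 with the monocyte labels pooled, -1.82 in thinned cells and -0.42 against Pre-IS. Chemokine receptors stood at -0.62, at 0.01 with no UMI minimum and at -0.27 against Pre-IS. Highest by the naming rule were PADI2, a peptidylarginine deiminase, and SLC7A6OS, with 35 and 33 UMIs against 0, at least 4.45-fold and 4.20-fold higher.

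In MS4A7+ monocytes, glucocorticoid-induced genes had 9 of 15 lower, 0 higher and a median of -0.68 (-0.97 to -0.52), and -0.02 against Pre-IS. TXNIP, a thioredoxin inhibitor of this list, was 2.78-fold lower (2.38 to 3.24). Classical monocyte genes were lower in 4 of 5 members with a median of -0.99, or -0.17 with the labels pooled and -0.46 against Pre-IS, and VCAN was 3.39-fold lower (2.25 to 5.11). FOS was 4.94-fold lower (3.14 to 7.84), TIMP1, an inhibitor of metalloproteinases, 4.11-fold (3.38 to 5.01) and ZC3H10 4.47-fold (3.78 to 5.28). Thinning took the log2 ratio of FOS from -2.30 to -1.62. The inflammatory cytokine TNF was 12.2-fold higher (3.26 to 102), with 84 UMIs against 2. LBH, a transcription cofactor, was 5.50-fold (2.06 to 20.7) and the translation initiation helicase DHX29 7.66-fold higher (2.02 to 64.9). Apoptosis and p53 genes had a median of -0.42 in this class and in T cells, with 6 of 12 and 3 of 13 lower, and turned to 0.11 and 0.20 against Pre-IS. Chemokine receptors and homing genes stood at 0.52 in T cells, and at 0.19 with their 3 genes of 0 UMIs at their bound. The random range of -0.30 to 0.26 was taken without that step, so it cannot place the lower value. Monocyte genes under the T cell label had a median of -1.59 over 6 members, and 0.11 against Pre-IS, among them the alarmin S100A8, 4.14-fold lower (1.79 to 8.53).

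The comparison of 8 wpt with Post-IS asks the same question at the later time. NK cells were 17.1-fold higher by share, at 25.5% (23.9 to 27.3), and the B lineage 4.98-fold higher at 10.7% (9.57 to 12). Naive B cells stood at 3.84% (3.13 to 4.65) against 0.166% (0.00420 to 0.921). T cells were 2.39-fold higher, at 45.5% (43.6 to 47.5). CD14+ monocytes were 4.07-fold lower at 13.4% (12.1 to 14.8), and MS4A7+ monocytes 8.62-fold lower at 2.52% (1.95 to 3.2).

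T cells at 8 wpt held more effector transcripts than Post-IS T cells. GZMB was 5.54-fold higher (4.23 to 7.41) at 2044 CPM, CX3CR1 at least 9.28-fold (433 UMIs against 0) and ZEB2, a transcription factor of terminal effector cells, at least 4.44-fold (207 against 0). Of 23 cytotoxic genes 19 were higher and 0 lower, with a median of 1.27 (1.12 to 1.86), 1.17 with 4 genes at their bound, and 0.14 against Pre-IS. Naive and central memory genes had a median of -0.68 (-0.82 to -0.34), with 6 of 12 lower, and -0.22 against Pre-IS. LEF1 was 2.27-fold (1.77 to 2.88) and the interleukin 7 receptor IL7R 1.73-fold lower (1.49 to 1.99). Glucocorticoid-induced genes had 7 of 14 lower, 1 higher and a median of -0.62 (-0.89 to -0.31), or -0.14 against Pre-IS. Interferon gamma genes had a median of 0.50 (0.37 to 0.92), and 0.21 against Pre-IS, inside the random range, with IRF1 2.94-fold higher (1.77 to 5.29). Type I interferon genes stood at 0.26 in T cells and 0.14 in CD14+ monocytes, inside the random range in both. CCR9 was 6.60-fold (3.26 to 12.7), RFX1 5.39-fold (2.91 to 9.53) and ZC3H10 2.61-fold lower (2.44 to 2.79). The log2 ratio of CCR9 was -2.75, and -3.83 in thinned cells. Apoptosis and p53 genes stood at -0.47, or -0.02 in thinned cells, and monocyte genes at -1.09 in T cells (-1.54 to 0.76), the latter over 5 members and -2.03 with possible doublets left out. Against Pre-IS these lists turned to 0.10 and 0.41.

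In CD14+ monocytes at 8 wpt, steroid-responsive and early-response genes were lower than at Post-IS and MHC class II genes higher. The glucocorticoid-induced list had 12 of 14 lower, 0 higher and a median of -1.11 (-1.37 to -0.97), or -0.33 against Pre-IS, with DUSP1 7.67-fold lower (6.77 to 8.72). Immediate early and heat shock genes had 11 of 19 lower and a median of -0.64 (-1.21 to -0.45), or -0.27 against Pre-IS, with JUN 15.4-fold (11.3 to 21.5) and EGR1 16.8-fold lower (11.1 to 26.5). NF-kB genes had 6 of 11 lower and a median of -0.60 (-0.97 to -0.44), or -0.08 against Pre-IS, with PTGS2 26.3-fold lower (13.3 to 59.1). MHC class II presentation genes had 4 of 12 higher, 1 lower and a median of 0.48 (0.35 to 0.55), or 0.27 in cells thinned to 1000 UMIs and 0.02 against Pre-IS. MAMU-DRA was 1.83-fold higher (1.73 to 1.93) and MAMU-DOA, with 1 Post-IS UMI, 16.0-fold (2.69 to 648). SLC7A6OS, with 28 UMIs against 0, was at least 4.03-fold higher. The remaining lists outside the random range had medians of -0.59 for nonclassical monocyte, -0.27 for classical monocyte, -0.46 for apoptosis and p53, and -0.36 for chemokine receptors, the last 0.22 with no UMI minimum. Against Pre-IS they were -0.20, 0.03, -0.40 and -0.14.

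MS4A7+ monocytes showed the same pair of lists. FKBP5 was 12.4-fold (4.54 to 47.4), DUSP1 6.56-fold (4.41 to 10.1) and DDIT4 9.86-fold lower (3.05 to 50.7). The glucocorticoid-induced list had 10 of 11 lower, 0 higher and a median of -1.37 (-1.75 to -1.06), and -0.20 against Pre-IS. MHC class II genes had 5 of 9 higher, 0 lower and a median of 0.60 (0.44 to 0.74), 0.75 under TMM scaling and 0.25 against Pre-IS, with MAMU-DRA 1.88-fold (1.62 to 2.19) and the invariant chain CD74 1.62-fold higher (1.53 to 1.71). NF-kB genes stood at -0.80 over 5 members and apoptosis and p53 genes at -0.87 over 8, or -0.11 with a minimum of 50 UMIs. Against Pre-IS they were -1.13 and -0.27. C1QA, a complement C1q chain, was 3.14-fold (1.77 to 5.88), the metallothionein MT1E 2.03-fold (1.68 to 2.47) and LY6D 9.47-fold higher (2.30 to 83.5), the last on 2 Post-IS UMIs. The log2 ratio of MT1E was 1.02, but 0.48 in thinned cells and 1.42 with each cell weighted equally. The scaling factor of TMM differed from the library total by -0.15 on the log2 scale in this class.

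**Figure D3:**
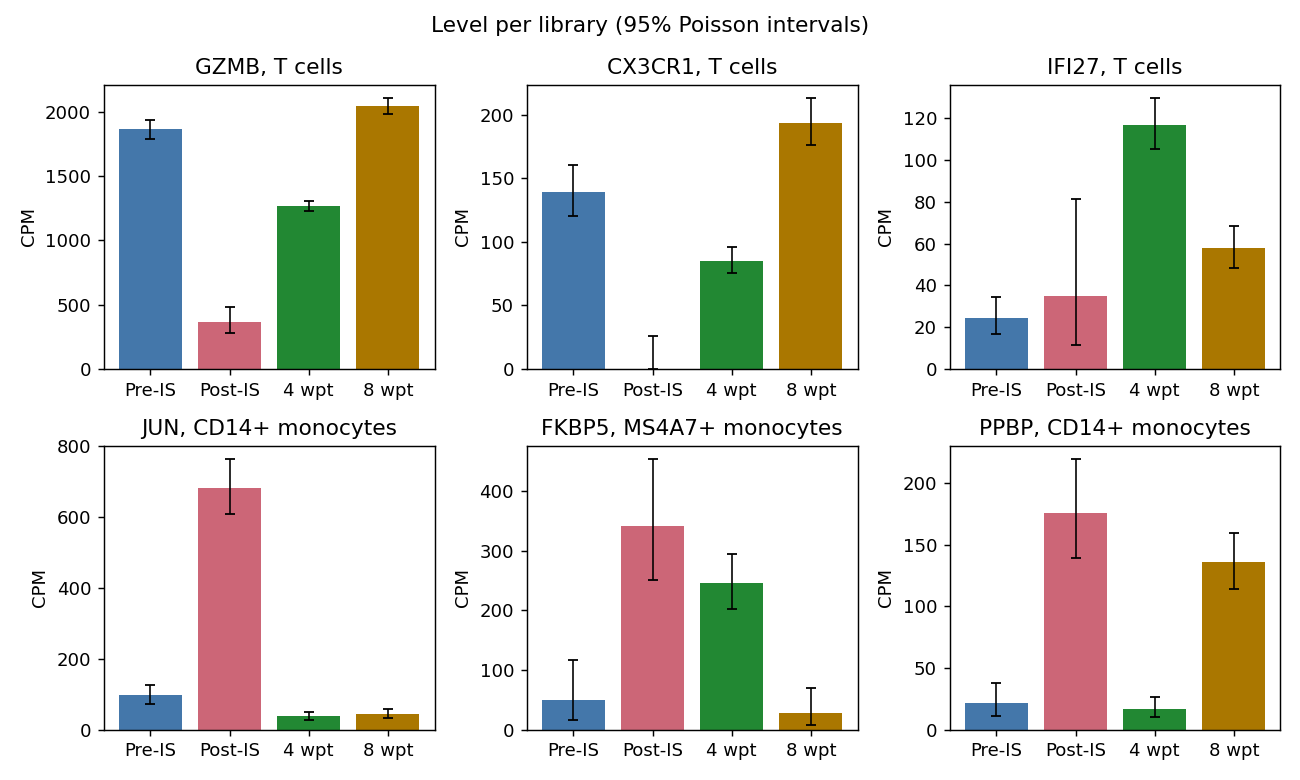
Level (CPM, vertical axes) of 6 genes in the cell class named above each panel, 1 bar per library (horizontal axes), with 95% Poisson intervals as error bars. GZMB in T cells is lowest for Post-IS at 369 CPM, IFI27 in T cells is highest at 4 wpt at 117 CPM, and FKBP5 in MS4A7+ monocytes is 341 CPM for Post-IS and 245 CPM at 4 wpt against 27.5 CPM at 8 wpt.

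Between the samples with a graft, the shares of several cell classes differed. Lymphocytes stood at 83.0% at 8 wpt against 70.6% at 4 wpt. NK cells were 1.78-fold higher by share, at 25.5% (23.9 to 27.3) against 14.3% (12.8 to 16.0). Naive B cells were 5.16-fold higher, at 3.84% (3.13 to 4.65) against 0.744% (0.407 to 1.25). MS4A7+ monocytes were 4.37-fold lower, at 2.52% (1.95 to 3.2) against 11% (9.62 to 12.5), and CD14+ monocytes 1.24-fold lower, at 13.4% (12.1 to 14.8) against 16.6% (14.9 to 18.3). The B lineage was 1.58-fold higher, and proliferating NK and T cells 1.87-fold lower at 1.16% (0.786 to 1.66). The T cell shares of 45.5% and 47.2% had overlapping intervals.

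Glucocorticoid-induced genes had negative medians for 8 wpt over 4 wpt in all 5 classes compared, though a small one in CD14+ monocytes. Their medians were -0.50 (-0.67 to -0.25) in T cells with 8 of 17 lower, -0.82 (-1.25 to -0.40) in MS4A7+ monocytes with 8 of 13 lower, -0.28 (-0.51 to -0.13) in NK cells, -0.37 (-0.57 to -0.06) in B cells and -0.15 (-0.34 to -0.05) in CD14+ monocytes. FKBP5 was 2.37-fold lower (2.01 to 2.81) in T cells, 2.88-fold (2.13 to 3.94) in NK cells, 8.94-fold (3.40 to 33.3) in MS4A7+ monocytes, 2.33-fold (1.24 to 4.65) in B cells and 2.11-fold (1.58 to 2.85) in CD14+ monocytes. The B cell median was 0.11 in cells thinned to 1000 UMIs. The CD14+ monocyte median lay just beyond the random limit of -0.143, and ranged from -0.46 to -0.13 under alternatives. Type I interferon genes were lower in T cells, with a median of -0.36 (-0.46 to -0.13) and 7 of 31 genes lower, and in CD14+ monocytes, with -0.40 (-0.58 to -0.17) and 10 of 25. IFI27 was 2.03-fold (1.65 to 2.5) and 2.92-fold lower (1.92 to 4.55) in these classes. Interferon gamma genes stood at -0.25 in CD14+ monocytes, where IDO1, the tryptophan-degrading enzyme, was 1.72-fold lower (1.44 to 2.06).

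Cytotoxic transcripts were higher under the T cell label at 8 wpt than at 4 wpt. Cytotoxic genes had 10 of 23 higher, 0 lower and a median of 0.40 (0.36 to 0.62), or 0.66 in cells thinned to 1000 UMIs. In T cells with a CD3 UMI and no UMI of the NK transcripts KLRF1 and NCR1, a selection made after the data were seen, it was 0.73. FCER1G, another NK transcript, stood at 9.46 CPM in T cells and 1191 CPM in NK cells at 4 wpt, and at 17.9 and 1320 CPM at 8 wpt. The sphingosine phosphate receptor S1PR5 was 3.51-fold higher (2.33 to 5.39), CX3CR1 2.28-fold (1.95 to 2.66) and the lectin receptors KLRD1 and KLRF1 2.27-fold (2.06 to 2.5) and 2.71-fold (2.11 to 3.50), both also NK transcripts. The orphan receptor GPR141 was 3.21-fold higher (2.58 to 4.01). Naive and central memory genes had a median of -0.25 (-0.35 to -0.16) and regulatory T genes of -0.34 (-0.75 to -0.10), with the checkpoint receptor TIGIT 1.68-fold lower (1.4 to 2.03). The regulatory T median lay just beyond the random limit of -0.335. Linker histones H1-2 and H1-4 were 4.79-fold (2.98 to 8.09) and 3.06-fold lower (2.19 to 4.35). In cells thinned to 1000 UMIs the log2 ratio of H1-4 went from -1.6 to -1.131, and that of KLRF1 from 1.433 to 1.815. Apoptosis and p53 genes stood at -0.24 and chemokine receptors at -0.19. Monocyte genes stood at 0.51 in T cells, and at -0.11 with each cell weighted equally.

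NK cells at 8 wpt were higher in HES4, a transcriptional repressor, by 10.5-fold (3.33 to 53.5), in interferon gamma itself (IFNG) by 3.99-fold (2.05 to 8.50), and in RHBDF2, an inactive rhomboid protein, by 4.04-fold (2.01 to 8.97). The chemokine receptor CXCR4 was 5.13-fold (2.55 to 11.4) and H1-4 4.09-fold lower (2.69 to 6.40). Proliferation genes had medians of -0.53 in NK cells (-0.73 to 0.03), with the cycling marker MKI67 3.0-fold lower (1.46 to 6.66), and of -0.53 in B cells (-0.84 to -0.13), with the ribonucleotide reductase subunit RRM2 16.7-fold lower (4.34 to 143) on 2 UMIs. Both directions turned in cells thinned to 1000 UMIs, at 0.17 in NK cells and 0.08 in B cells. Apoptosis and p53 genes stood at -0.38 in NK cells, and at 0.06 with a minimum of 50 UMIs. B cell identity lists were inside the random range, at 0.18 for naive B and B cell receptor genes and -0.05 for memory B and plasmablast genes. So were these lists of other lineages, at -0.28 for B cell genes in NK cells, 0.41 for T cell genes in B cells and -0.08 for T cell genes in CD14+ monocytes. Red cell genes had fewer than 3 measured members in every class and gave no value.

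CD14+ monocytes at 8 wpt were 7.98-fold higher (4.97 to 13.5) in PPBP and 9.96-fold (3.96 to 32.2) in PF4, both platelet chemokines, whose UMIs sat in few cells, and the 3 platelet genes had a median of 2.97. CD1C, which presents lipid antigens, was 2.38-fold higher (1.99 to 2.85). Its log2 ratio of 1.249 was 1.647 with each cell weighted equally and 1.703 in thinned cells. MHC class II genes stood at 0.32 (0.25 to 0.40), with MAMU-DRA 1.28-fold higher (1.24 to 1.32). Classical monocyte genes had a median of -0.33 (-0.46 to -0.27), or -0.02 with the monocyte labels pooled and -0.60 in thinned cells, with THBS1 4.14-fold (2.5 to 7.20) and S100A9 1.41-fold lower (1.33 to 1.49). KMT2D, a histone methyltransferase, was 5.48-fold (2.11 to 18.1) and RBIS, a ribosome biogenesis factor, 2.51-fold lower (1.99 to 3.19). The log2 ratio of KMT2D, on 5 UMIs at 8 wpt, went from -2.34 to -4.63 in thinned cells. Nonclassical genes had 5 of 12 higher and a median of 0.55 (0.30 to 0.69), but -0.49 with the monocyte labels pooled. Neutrophil genes stood at -0.35 over 4 members.

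In MS4A7+ monocytes the median over all genes was -0.11, which was not subtracted from the list values. NF-kB genes had a median of -0.74 (-1.21 to -0.33), with the survival factor BCL2A1 3.30-fold (2.17 to 5.24) and TNF 5.13-fold lower (2.11 to 16.2). That median ranged from -1.09 to -0.39 under alternatives. MHC class II genes stood at 0.47 (0.26 to 0.58), just beyond the random limit of 0.463, with MAMU-DRA 1.91-fold higher (1.71 to 2.13). Classical monocyte genes stood at 0.71 over 6 members, with the antibacterial enzyme lysozyme (LYZ) 2.86-fold higher (2.46 to 3.32), and at -0.02 with the labels pooled. Neutrophil genes stood at 0.55 over 5 members (-0.36 to 1.36), at the random limit of 0.553, and at -0.31 with a minimum of 50 UMIs.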

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

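The tests of free RNA, of the share of cytotoxic cells, of mitochondrial share, of early-response genes and of platelet material were chosen only after the result was seen, the strict T cells were chosen after the data were seen but before the value of that test, and the thinning for shallow cells was planned.

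Several gene lists stood on opposite sides in a pair of cell classes under the same comparison, and none of these differences was tested. From Pre-IS to Post-IS, NF-kB and inflammatory cytokine genes had a median log2 ratio of 0.69 in CD14+ monocytes and -0.57 in MS4A7+ monocytes, a difference of 1.26. At 4 wpt over Post-IS, chemokine receptor and homing genes stood at 0.52 in T cells and -0.62 in CD14+ monocytes, 1.14 apart. The T cell value was only 0.19 with 3 genes of 0 UMIs at their bound, a step that the random lists were not given. From 4 wpt to 8 wpt, classical monocyte genes stood at 0.71 in MS4A7+ and -0.33 in CD14+ monocytes, 1.04 apart, and neutrophil genes at 0.55 and -0.35, 0.908 apart. The MS4A7+ values rest on few genes and turned sign under other settings. Cells labelled as platelets were 12 at 4 wpt and 0 in the other libraries, above the share that a count of 0 allows in each of them, though the interval of the 4 wpt share (0.330 to 1.11) overlaps that of Post-IS, which ends at 0.610%.

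Cytotoxic genes were lower in Post-IS than in Pre-IS T cells. The tables argue against NK cells carried under the T cell label, because in T cells with CD3 UMIs and no KLRF1 or NCR1 UMI (106 against 719 cells) the list median was still -1.10 (-1.63 to -0.92), outside the random range of -0.26 to 0.23. They also argue against free RNA from NK cells as the main source. The drop in list CPM in CD14+ monocytes was 4.78% of that in T cells (2.31 to 7.16). This could understate free RNA, because list member CX3CR1 also stands on the nonclassical monocyte list, which was higher in these Post-IS monocytes. The whole Pre-IS monocyte level, which bounds free RNA there, was 18.9% of the T cell drop (16.9 to 21.2). A first bound for this test, a level under 20% of that drop, was met by less than its counting error. A lower share of cytotoxic cells among T cells stays open as a candidate explanation, with at least 10 list UMIs of 1000 in 9.41% of Post-IS T cells (8 of 85, 4.15 to 17.7) against 32.7% of Pre-IS T cells (29.3 to 36.2). The list level inside those cells was 14.3% higher for Post-IS (-20.1 to 76.3), on 8 Post-IS cells. The upper end passed the 25% allowed, so the rule of the test gave no answer. Cells under 10 list UMIs leave this group. The level inside it therefore cannot separate a lower share from lower levels per cell.

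Glucocorticoid-induced genes were higher in Post-IS than in Pre-IS CD14+ monocytes. The tables argue against shallow cells, because with each cell thinned to 1000 UMIs the list median was 0.89 (0.70 to 1.27) against a random range up to 0.38, and against damaged cells rich in mitochondrial RNA, because in cells at or below 0.688% (56 against 128 cells) it was 1.05 (0.70 to 1.34) against a range up to 0.49. The list does not rest on early-response genes alone. Its 7 members that are not early-response genes, picked after the result was seen, had a median of 0.85 (0.61 to 1.00) against a random range up to 0.44. The same members stood at 1.12 in MS4A7+ monocytes, and at 0.38 in T cells, inside the random range there. Handling as a cause is not excluded, because whether it alters these members was not tested. Immediate early and heat shock genes were also higher in the CD14+ monocytes, with a median of 0.74. A steroid in the immunosuppression regimen is untested, since the labels name no drug. Damage that leaves the mitochondrial share low was not tested, and 1 library per group leaves a difference between blood draws open.

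Platelet genes were higher in CD14+ monocytes at Post-IS and 8 wpt, where PPBP and PF4 together stood at 232 and 178 CPM against 21.9 CPM for Pre-IS and 21.3 CPM at 4 wpt. The tables argue against free platelet RNA as the whole source, because the upper limit in T cells was 11.1% of the monocyte level at Post-IS and 12.5% at 8 wpt. Platelet material carried by some of the monocytes is a candidate source. At 8 wpt 49 of 346 monocytes held these UMIs, against 128 to 146 cells when the UMIs were spread by depth, and at Post-IS 51 of 329 against 78 to 91. Whether such material had bound in the blood or during handling was not tested, and none of the platelet genes stands on another list.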

How the results depend on the processing

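The comparison with Pre-IS in place of Post-IS and the T cells without KLRF1 or NCR1 UMIs were chosen only after the result was seen, and the other alternatives were planned.

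For the 72 named gene ratios, 417 of 432 values under alternatives stayed within their intervals and none changed direction. The 15 that moved came from cells thinned to 1000 UMIs (12) and from weighting each cell equally (3). TMM, median-of-ratios, leaving out possible doublets and the restricted total moved 0 of them. For the 207 list medians, 1611 of 1735 values stayed within their intervals, 106 moved and 18 changed sign. Sign changes were counted only for lists outside the random range. Those of lists inside it stand among the values that stayed or moved. For the 16 shares, 50 of 52 stayed. Except where stated, the cause was not tested.

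Of lists outside the random range against Post-IS, 18 at 4 wpt and 18 at 8 wpt could be set against Pre-IS, and 11 and 12 of them were then inside it. At 4 wpt the cytotoxic list in T cells turned to -0.30 and the naive list to 0.016, nonclassical genes in CD14+ monocytes stood at -0.42 and glucocorticoid-induced genes in MS4A7+ monocytes at -0.025. NF-kB genes in CD14+ monocytes turned to 0.090, apoptosis genes to 0.20 in T cells and 0.11 in MS4A7+ monocytes, and monocyte genes in T cells to 0.11. At 8 wpt the cytotoxic list stood at 0.14 and the naive list at -0.22, the glucocorticoid list at -0.33 in CD14+ and -0.20 in MS4A7+ monocytes, and MHC class II genes at 0.021 and 0.25. Classical genes in CD14+ monocytes turned to 0.028, and in T cells apoptosis genes to 0.096 and monocyte genes to 0.41. Type I interferon genes in CD14+ monocytes at 4 wpt went from 0.54 to 0.33, inside the counting interval. In T cells with a CD3 UMI and no KLRF1 or NCR1 UMI the cytotoxic list moved to 0.73 for 8 wpt over 4 wpt, and stayed within its interval in the other 3 comparisons.

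Among cells of at least 1000 UMIs, T cells were 24.2% and monocytes 69.0% of Post-IS. Thinning gave -1.82 for nonclassical genes in CD14+ monocytes (4 wpt over Post-IS), 0.27 for MHC class II genes there (8 wpt over Post-IS) and 0.66 for cytotoxic genes in T cells (8 wpt over 4 wpt). Between 4 wpt and 8 wpt it turned proliferation to 0.17 in NK cells and 0.080 in B cells, glucocorticoid-induced genes in B cells to 0.11 and neutrophil genes in MS4A7+ monocytes to -0.014. Equal weight per cell gave -0.57 for MHC class II genes in CD14+ monocytes (Post-IS over Pre-IS) and 0.75 for nonclassical genes there (8 wpt over 4 wpt). It turned NF-kB genes in MS4A7+ monocytes (Post-IS over Pre-IS) to 0.043, and at 8 wpt over 4 wpt monocyte genes in T cells to -0.11 and B cell proliferation to 0.056. B cell proliferation was -0.068 without possible doublets.

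TMM gave 0.75 for MHC class II genes in MS4A7+ monocytes (8 wpt over Post-IS), and median-of-ratios -0.53 for them in CD14+ monocytes (Post-IS over Pre-IS). An offset of 2 UMIs gave 0.73 for glucocorticoid-induced genes (Post-IS over Pre-IS) and 0.70 for cytotoxic genes (4 wpt over Post-IS) in T cells.

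Pooling both monocyte labels gave -0.12 for nonclassical genes (4 wpt over Post-IS) and -1.43 for glucocorticoid-induced genes (8 wpt over Post-IS). It turned NF-kB genes of MS4A7+ monocytes (Post-IS over Pre-IS) to 0.53. At 8 wpt over 4 wpt it turned nonclassical genes of CD14+ monocytes to -0.49, and classical and neutrophil genes of MS4A7+ monocytes to -0.024 and -0.15. Pooling adds the other monocyte class by construction. A minimum of 50 UMIs, which leaves fewer genes, turned apoptosis genes in MS4A7+ monocytes (Post-IS over Pre-IS) to -0.0026. At 8 wpt over 4 wpt it turned proliferation and apoptosis genes in NK cells to 0.011 and 0.059, and neutrophil genes in MS4A7+ monocytes to -0.31. No minimum turned classical genes in MS4A7+ monocytes (Post-IS over Pre-IS) to -0.22 and chemokine receptors in CD14+ monocytes to 0.011 at 4 wpt and 0.22 at 8 wpt, both over Post-IS.

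With 1 library per group, none was left out in turn and no pairs were compared. Lists left with under 3 genes, and lists outside the B and monocyte lineages under pooling, gave no value. Depth limits MS4A7+ monocytes of Pre-IS and Post-IS and T cells of Post-IS most among the Post-IS over Pre-IS classes, with 75, 131 and 115 cells.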

Other observations

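The comparisons of 4 wpt and 8 wpt with Pre-IS in this part were chosen only after the result was seen for Post-IS.

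Set against blood from before immunosuppression, the 4 wpt sample differed in B cells, interferon-induced genes and cycling cells, among others. The B lineage was 3.52-fold and naive B cells 7.67-fold lower by share than at Pre-IS, MS4A7+ monocytes were 2.83-fold and proliferating NK and T cells 5.25-fold higher, and T cells differed by 1.08-fold. Type I interferon genes had medians of 0.51 (0.32 to 0.74) in T cells, 0.41 (0.16 to 0.61) in NK cells, 0.33 (0.19 to 0.74) in CD14+ monocytes and 0.49 (0.16 to 0.77) in B cells, each outside the random range, and 0.07 in MS4A7+ monocytes, inside it. IFI27 was 4.79-fold higher (3.35 to 7.06) in T cells, 10.3-fold (5.52 to 21.8) in NK cells and 23.1-fold (6.22 to 193) in CD14+ monocytes. In B cells, naive B and B cell receptor genes had a median of -0.68 (-0.85 to -0.45), with 9 of 16 at least 1.5-fold lower, and proliferation genes one of 0.49. These B cells were deeper at 4 wpt, at a median of 3890 UMIs against 1512. The B cell proliferation median for 8 wpt over 4 wpt turned to 0.080 in thinned cells and was -0.068 without possible doublets. T cell genes under the B cell label stood at -0.97 over 4 members, also outside the random range. Possible doublets were 15 of 114 B cells at 4 wpt against 16 of 351 for Pre-IS, so cells of mixed label are not excluded there. NK cells held more FKBP5, 3.56-fold (2.18 to 6.16), and a glucocorticoid-induced list median of 0.54 (0.32 to 0.76), and B cells had 0.40 (0.05 to 0.56). That list was inside the random range in T cells at 0.18, CD14+ monocytes at -0.20 and MS4A7+ monocytes at -0.02. Immediate early and heat shock genes stood at 0.41 (0.11 to 0.56) in NK cells, 0.27 in T cells and 0.38 (0.25 to 0.66) in B cells, and at -0.36 in CD14+ monocytes (-0.67 to 0.07). Cytotoxic genes in T cells stood at -0.30 (-0.39 to -0.16).

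At 8 wpt, NK cells were 1.92-fold higher and the B lineage 2.23-fold lower by share than at Pre-IS, and CD14+ monocytes differed by 1.01-fold. Type I interferon genes had medians of 0.23 (0.10 to 0.40) in T cells and 0.54 (0.04 to 0.96) in naive B cells. Inside the random range were NK cells at 0.20, CD14+ monocytes at 0.12, B cells at 0.14 and MS4A7+ monocytes at -0.27. MHC class II genes in T cells stood at 0.47 (0.15 to 0.69) at 4 wpt and 0.42 (0.18 to 0.83) at 8 wpt, the latter with MAMU-DRA 2.40-fold higher (1.73 to 3.41). Possible doublets were 42 of 889 T cells at 4 wpt and 32 of 1174 at 8 wpt, against 10 of 841 for Pre-IS. Without a value that leaves them out, class II RNA from other cells is not excluded. Naive B and B cell receptor genes in B cells stood at -0.36, with 7 of 16 lower.

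Over all cells, Y-linked DDX3Y stood at 70.3, 73.3, 69.6 and 65.3 CPM and UTY at 48.6, 48.0, 48.6 and 44.7 CPM for Pre-IS, Post-IS, 4 wpt and 8 wpt. Among islet endocrine genes, GHRL had 4, 0, 5 and 2 UMIs in the same order, while SCG5 stood at 11.6, 8.85, 9.70 and 12.8 CPM. ZC3H10 in NK cells stood at 3108, 6206, 1550 and 2079 CPM.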
